A study of Homo sapiens with 6 samples.

How the data were processed

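RNA was sequenced from HEK293T cells expressing the adenine base editor ABE7.10 and treated with DMSO, ITD1 or SB505124, with 2 libraries in each of 3 groups. Samples were assigned to groups from their labels. The deposited sheets hold raw read counts per gene, whole numbers that were not normalized, per the file headers and the values. Per the submitters' processing notes, the tools were Cutadapt 1.15, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0, with the hg38 build, and their settings, the annotation and the use of strand are not given in the sources used here. Reads that overlap 2 genes, or that match near-identical copies, may therefore be split or dropped in ways that cannot be checked from the counts, and neighbouring or antisense genes are uncertain for the same reason.

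One sheet covers SB505124 and DMSO with 17190 genes and the other ITD1 and DMSO with 17022 genes. The 16777 genes in both have identical DMSO counts, with 0 genes that differ, and the 413 and 245 genes of a single sheet have 0 DMSO counts, so 97.6% and 98.6% of each sheet's genes were shared and a fit of all 6 libraries was made as planned. Total counts per library ran from 14803276 to 17401932. Gene symbols were those of the sheets. Positions, GC content and transcript length came from GENCODE v29 on GRCh38, matched by gene identifier for 99.9% of tested genes.

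Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR filter for low expression, at its default minimum count of 10, kept 14000 genes and removed 2777. Libraries were scaled by TMM, and groups were compared by the quasi-likelihood F test with all 3 groups sharing 1 estimate of the spread, which left 3 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 change is its size divided by the square root of F. The biological coefficient of variation was 8.76%. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 2.66 for DMSO, 3.40 for ITD1 and 18.9 for SB505124.

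The genes named were fixed by a rule before the data were examined, as were the tests, the main alternatives and 33 gene lists. The rule took, per compound, the 8 called genes with the largest increase and the 8 with the largest decrease among those at or above the median level with groups that did not overlap; up to 4 called members of each list with the smallest adjusted p; 11 genes named whether called or not, of which 1 is not used here; and 5 genes per direction for the direct contrast. Lists with at least 5 tested members, 30 in all, were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with counts of called members adjusted over all genes and over the list alone. In ITD1 against DMSO the median, mean and camera direction differed in sign for the TGF-beta targets, mismatch repair, nucleotide excision repair, extracellular matrix and neuronal lists, and in SB505124 against DMSO for the TGF-beta pathway components. In SB505124 against ITD1 they differed for 7 lists. None of these lists passed.

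On simulated counts with 200 changed genes of 14000, the edgeR test for ITD1 against DMSO recovered 66.1% of 1.5-fold, 72.9% of 2-fold and 92.6% of 3-fold changes, and that for SB505124 against DMSO 54.1%, 82.1% and 93.1%, with 6.06% of 165 calls false in each. Overlap by chance was simulated with 50 draws of unchanged groups against the same controls. In these simulations each gene had 1 spread in all groups. The observed chi-square per degree of freedom was 2.66 for DMSO, 3.40 for ITD1 and 18.9 for SB505124. The recovered and false shares may therefore not hold for the observed comparisons. The 200 changed genes were also far fewer than the 1268 and 7400 called with ITD1 and SB505124.

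Alternatives were a replicate block, RLE size factors, no filter or a minimum of 5 CPM, the DESeq2 Wald test, a minimum 2-fold change, leaving out each library and using 4 libraries. Added after the data were seen were a correction of each library's trend on GC content and transcript length, a length correction alone, scaling without the mitochondrially encoded genes, and a test of each added family without the genes the rule names. The planned change of pseudocount applied to normalized values only and was not run. Genes listed in a single sheet were left out of the tests, and no counts column was left out.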

Results

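Gene-level read counts were compared in HEK293T cells, an established line of human embryonic kidney cells that carries the SV40 large T antigen. The cells had been transfected with a plasmid for ABE7.10, an adenine base editor that joins a deaminase to a Cas9 nickase and changes A to G in DNA, together with a guide RNA for 1 site. They were then kept for 72 h with DMSO, the solvent control, with ITD1, an inhibitor of TGF-beta signalling, or with SB505124, an inhibitor of the type I receptors of TGF-beta, activin and nodal. The doses are not given in the sources used here, and the compounds are compared without matching of dose. Each of the 3 groups had 2 libraries. The libraries held 14810021 and 15031642 counts for DMSO, 14803276 and 17401932 for ITD1, and 16456165 and 14901132 for SB505124. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Levels below are TMM-scaled CPM (library-size scaled counts), mean ± SD of n = 2 libraries, and changes are log2 ratios with their standard error (SE).

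The first comparison asked which genes differed between ITD1 and DMSO. SLC3A2, the heavy chain shared by several amino acid exchangers, stood highest (ENSG00000168003, chromosome 11, 62856102 to 62888875 in GENCODE v29 on GRCh38), with 1571 ± 39.3 CPM against 338 ± 1.86 CPM in DMSO. Its change of 2.22 on the log2 scale (SE 0.11) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p = 1.51e-07. The riboflavin transporter SLC52A2 (0.97), the mannosyltransferases ALG3 (0.96) and ALG1 (0.88), the fatty acid elongation enzyme TECR (0.92), the lysosomal cysteine transporter MFSD12 (0.90) and the stress cytokine GDF15 (0.97) also rose. Among the steepest falls at or above the median level, the kinetochore motor CENPE (ENSG00000138778, chromosome 4, 103105806 to 103198409) went from 173 ± 6.48 to 32.6 ± 5.17 CPM (log2 change -2.41, SE 0.37), and CEP290 (-1.96), KIF20B (-1.78), GOLGA4 (-1.69), CENPF (-1.55), AKAP9 (-1.52), ASPM (-1.51) and ESF1 (-1.44) fell as well. After a correction for GC content and length, chosen after the data were seen, CENPE was at -2.00, GOLGA4 at -1.41 and AKAP9 at -1.20. The calls of all 8 were lost without either DMSO replicate or without ITD1 replicate 2. In the SB505124 libraries, CENPE had 50.8 ± 41.8 CPM, a spread between replicates close to the mean itself.

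Genes that p53 activates rose as a group with ITD1: 12 of 22 tested members rose and 0 fell, with 14 higher when adjusted over the list alone. The median change was 0.49, and limma's camera with Benjamini-Hochberg adjustment gave an adjusted p = 1.48e-12, or an adjusted p = 0.15 with an estimated correlation. Its members with the smallest p-values were the pro-apoptotic BBC3 (0.94, from 17.5 ± 0.121 to 33.7 ± 1.64 CPM), the quinone oxidoreductase TP53I3 (0.87), the sestrin SESN2 (0.74) and the death receptor TNFRSF10B (0.66). Of the 26 genes of the unfolded protein and integrated stress response, 8 rose, among them the transcription factors ATF3 (0.79) and XBP1 (0.59) and the chaperone partner DNAJB9 (0.83), and none fell. Adjusted over the list alone, 16 of these were higher and 1 lower, and camera with Benjamini-Hochberg adjustment gave an adjusted p = 1.26e-09 (adjusted p = 0.536 with an estimated correlation). The mitochondrially encoded genes, listed beforehand as a possible sign of RNA quality, rose in the same libraries as the p53 and stress response genes, with a median of 0.61. RNA quality itself was not measured. The number of called p53 and stress response genes depended on which libraries were in the fit, while both medians stayed above 0 without any 1 library. The count of higher p53 targets was 0 without DMSO replicate 1, 1 without DMSO replicate 2, 6 without ITD1 replicate 1 and 1 without ITD1 replicate 2. That of higher stress response genes was 0 without DMSO replicate 1, 1 without DMSO replicate 2, 4 without ITD1 replicate 1, 0 without ITD1 replicate 2, 19 without SB505124 replicate 1 and 19 without SB505124 replicate 2.

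Of the 13 mitochondrially encoded genes, 12 rose with ITD1, a count that was the same adjusted over the list alone, and their median change was 0.61 (camera with Benjamini-Hochberg adjustment, adjusted p = 8.72e-20, and adjusted p = 0.15 with an estimated correlation). These included MT-ND6 (0.77), MT-CO2 (0.73) and MT-CYB (0.67). These genes held 4.21% and 4.49% of the counts in the ITD1 libraries against 3.05% and 3.20% in DMSO. The count of higher genes was 0 without DMSO replicate 1, 5 without DMSO replicate 2, 7 without ITD1 replicate 1 and 1 without ITD1 replicate 2. Among 40 cytosolic ribosomal protein genes 6 rose, led by RPLP1 (0.47), RPS19 (0.41) and RPLP0 (0.41), and 17 were higher when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 1.55e-08, and adjusted p = 0.561 with an estimated correlation). For the ribosomal protein genes it was 0 without DMSO replicate 1, 0 without DMSO replicate 2, 0 without ITD1 replicate 1, 0 without ITD1 replicate 2, 34 without SB505124 replicate 1 and 31 without SB505124 replicate 2, and 14 after the GC and length correction, which put RPS19 at 0.27.

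BMP target genes and components went the other way with ITD1: 6 of 22 fell and none rose, with 8 lower when adjusted over the list alone. The members named by the smallest p-values were SMAD9 (-0.63), the helix-loop-helix inhibitors ID2 (-0.61) and ID1 (-1.11), and the BMP antagonist NOG (-1.69). Camera with Benjamini-Hochberg adjustment gave this list an adjusted p = 6.09e-05, or an adjusted p = 0.167 with an estimated correlation. The count of lower BMP genes was 0 without DMSO replicate 1, 0 without DMSO replicate 2, 2 without ITD1 replicate 1, 0 without ITD1 replicate 2, 10 without SB505124 replicate 1 and 11 without SB505124 replicate 2. In double-strand break and Fanconi repair, 9 of 39 genes fell and 1 rose (14 and 1 adjusted over the list alone), with RIF1 (-1.10), LIG4 (-0.87) and FANCM (-0.84) among those that fell. After the GC and length correction these were at -0.76, -0.53 and -0.51, 8 genes of the list were lower, and its median moved from -0.23 to -0.08. The list then had an adjusted p = 0.00431 by camera with Benjamini-Hochberg adjustment. For these, camera with Benjamini-Hochberg adjustment gave an adjusted p = 2.19e-04, and an adjusted p = 0.536 with an estimated correlation. The count of lower repair genes was 0 without DMSO replicate 1, 0 without DMSO replicate 2, 2 without ITD1 replicate 1, 0 without ITD1 replicate 2, 18 without SB505124 replicate 1 and 19 without SB505124 replicate 2. In the cell cycle list 6 of 32 genes fell, among them TOP2A (-0.90) and MKI67 (-0.43), and 7 fell and 1 rose adjusted over the list alone, while the list as a whole did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.107, and adjusted p = 0.011 after the GC and length correction). The count of lower cell cycle genes was 0 without DMSO replicate 1, 0 without DMSO replicate 2, 3 without ITD1 replicate 1, 0 without ITD1 replicate 2, 9 without SB505124 replicate 1 and 10 without SB505124 replicate 2, and camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.00104 without SB505124 replicate 1 and 0.000412 without SB505124 replicate 2.

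Other lists passed camera with Benjamini-Hochberg adjustment with ITD1 on few called members. The NRF2 targets had 2 of 18 genes higher, HMOX1 (0.81) and SQSTM1 (0.55), with an adjusted p = 0.0322 (adjusted p = 0.561 with an estimated correlation). Sterol synthesis had 2 of 24 higher, among them DHCR7 (0.53), with an adjusted p = 0.0412 (adjusted p = 0.536 with an estimated correlation). NRF2 and sterol counts were the same adjusted over the list alone. Ribosome biogenesis had 2 of 28 higher, and 4 higher and 2 lower adjusted over the list alone, with an adjusted p = 0.0498 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.538 with an estimated correlation). Interferon genes had a median of -0.43, with 0 of 22 called by edgeR over all genes or over the list alone, 10 at an unadjusted p under 0.05 and 0 called by DESeq2 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.01; adjusted p = 0.536 with an estimated correlation). Single libraries ended each of these: the adjusted p by camera with Benjamini-Hochberg adjustment was 0.0703 without DMSO replicate 1 and 0.097 without ITD1 replicate 2 for NRF2 targets, 0.11 without DMSO replicate 1 and 0.155 without ITD1 replicate 2 for sterol synthesis, 0.0703 without DMSO replicate 1 and 0.121 without ITD1 replicate 2 for ribosome biogenesis, and 0.054 without SB505124 replicate 1 and 0.0955 without SB505124 replicate 2 for interferon genes. After the GC and length correction it was 0.0575 for sterol synthesis and 0.179 for ribosome biogenesis by camera with Benjamini-Hochberg adjustment. Nucleotide excision repair had 1 of 21 higher and 1 lower, mismatch repair 2 of 20 lower, extracellular matrix genes 2 of 32 higher and 4 lower, and neuronal genes 1 of 13 higher, and none of these lists passed camera.

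TGF-beta target genes, the readout closest to the named activity of the compounds, did not move one way with ITD1. SKIL, a SMAD co-repressor induced by TGF-beta, fell from 59.1 ± 0.525 to 35 ± 2.11 CPM (-0.76, SE 0.11), and BMF fell (-0.77), while HMOX1 rose and the cell cycle inhibitor CDKN1A rose (0.66). CDKN1A is also in the p53 list and HMOX1 in the NRF2 list, which both rose, so neither is a readout of TGF-beta alone. BMF is likewise also in the cell death list. The other 23 of 27 tested targets did not pass, and adjusted over the list alone 2 were higher and 3 lower. SMAD7 had a change of -0.49 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.052), CCN2 of -0.28, PMEPA1 of 0.19 and the receptor TGFBR1 of -0.24, none of them called. The sign of TGFBR1 turned after the GC and length correction (0.048). That of CCN2 turned without DMSO replicate 1 (0.034), and its change was -0.49 without DMSO replicate 2, -0.14 without ITD1 replicate 1 and -0.46 without ITD1 replicate 2. Camera with Benjamini-Hochberg adjustment gave an adjusted p = 0.681 for the targets and 0.305 for pathway components, of which GDF15 rose and SMAD6 (-0.96) fell. Higher targets numbered 0 without DMSO replicate 1, 1 without DMSO replicate 2, 2 without ITD1 replicate 1, 0 without ITD1 replicate 2, 6 without SB505124 replicate 1 and 5 without SB505124 replicate 2. Lower targets numbered 0 without DMSO replicate 1, 0 without DMSO replicate 2, 1 without ITD1 replicate 1, 0 without ITD1 replicate 2, 3 without SB505124 replicate 1 and 4 without SB505124 replicate 2. Higher components numbered 0 without DMSO replicate 1, 6 without SB505124 replicate 1 and 4 without SB505124 replicate 2. Lower components numbered 0 without DMSO replicate 1, 0 without ITD1 replicate 2, 8 without SB505124 replicate 1 and 9 without SB505124 replicate 2. SKIL was at -0.30 after the GC and length correction, and its call was lost without DMSO replicate 1 (-0.74), DMSO replicate 2 (-0.71) or ITD1 replicate 2 (-0.70). SMAD7 was called in 7 of 14 alternative settings. In base excision repair, MPG, the glycosylase that removes hypoxanthine, the base of inosine, from DNA, rose (0.55, adjusted p = 0.021 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and no other of 23 members was called. The call of MPG was lost without either DMSO replicate, without either ITD1 replicate and after the GC and length correction (0.32). Higher base excision repair genes numbered 0 without DMSO replicate 1, 0 without DMSO replicate 2, 0 without ITD1 replicate 1, 0 without ITD1 replicate 2, 6 without SB505124 replicate 1 and 4 without SB505124 replicate 2. The adenosine deaminase ADAR (0.10) and the xenobiotic gene CYP1A1 (-0.65) were not called, ID3 fell (-0.47), and of 19 purine salvage and deaminase genes 0 were called by edgeR with ITD1, 4 had an unadjusted p under 0.05 and 0 were called by DESeq2.

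Over 14000 tested genes, 1268 were called with ITD1, 529 higher and 739 lower, and 97 of them changed by at least 2-fold, 7 higher and 90 lower. The balance of directions depended on the setting: DESeq2 called 695 higher and 632 lower, RLE scaling 647 and 660, and the GC and length correction 1069 and 813. It was 1 and 2 without DMSO replicate 1, 19 and 6 without DMSO replicate 2, 62 and 132 without ITD1 replicate 1, 21 and 6 without ITD1 replicate 2, 2787 and 2050 without SB505124 replicate 1, and 2208 and 2315 without SB505124 replicate 2. The total of 1268 also depended on which libraries were in the fit. Fits without a DMSO or ITD1 library hold fewer samples, and those without an SB505124 library lose the pair that spreads most. With the 4 libraries of this comparison alone the total was 4534.

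The genes called lower with ITD1 had a median GC content of 39.4% and a median transcript length of 5616 bases, against 48.7% and 3723 bases for tested genes. Those called higher had 56.7% and 2828 bases. In the decile of genes with the lowest GC content, 300 were lower and 7 higher with ITD1. In the decile with the highest GC content, 11 were lower and 129 higher. With SB505124, genes called lower had a median GC content of 46.0% and those called higher 52.0%, with 500 lower and 181 higher in the lowest decile and 271 lower and 471 higher in the highest. The median log2 change in the lowest decile minus that in the highest differed from DMSO by -0.47 for ITD1 and -0.35 for SB505124. Per library this trend was 0.26 and 0.31 in DMSO, -0.20 and -0.18 in ITD1, and 0.20 and -0.34 in SB505124, so the value for SB505124 came mostly from replicate 2. A trend of the same kind separated the 2 SB505124 replicates, whose median log2 difference went from 0.37 in the lowest decile to -0.19 in the highest, while the DMSO replicates stayed within -0.029 and 0.039.

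The second comparison asked which genes differed between SB505124 and DMSO. ANKRD1, a muscle ankyrin repeat protein and a target of YAP, rose from 3.22 ± 0.88 to 182 ± 6.62 CPM (ENSG00000148677, chromosome 10, 90912096 to 90921276), a log2 change of 5.82 (SE 0.17; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.34e-11). The dynein heavy chain DNAH17 (4.14), the adhesion protein NECTIN4 (3.83), the actin crosslinker FLNC (3.30), the inositol phosphatase INPP5D (3.04), the decoy death receptor TNFRSF10D (2.83), HID1 (2.69) and PLPP5 (2.68) rose as well. MYC, the growth transcription factor, fell from 176 ± 12.8 to 30.1 ± 0.452 CPM (-2.55, SE 0.11; adjusted p = 1.2e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the reductase DHRS2 (-2.82), carbonic anhydrase CA2 (-2.81), the semaphorin receptor NRP1 (-2.71) and ZNF503 (-2.66) fell.

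Mitochondrially encoded genes fell with SB505124, opposite to ITD1. MT-ND6 (ENSG00000198695, chromosome M, 14149 to 14673) dropped from 210.4 ± 10.6 to 24.7 ± 2 CPM (-3.09, SE 0.11), and MT-CO3 (-2.85), MT-ND5 (-2.58) and MT-CO1 (-2.50) fell as well. Of the 13 genes 10 fell and 1 rose, MT-ND2 (1.13, chosen after its values were seen), with the same numbers adjusted over the list alone. The median change was -1.27 (camera with Benjamini-Hochberg adjustment, adjusted p = 9.25e-18; adjusted p = 0.109 with an estimated correlation). These genes took 1.03% and 1.01% of the counts in the SB505124 libraries. Near-identical copies limit single values: the share of 50-base windows that occur in other annotated transcripts was 49.5% for MT-CO1, 46.7% for MT-ATP6, 43.6% for MT-ND2, 30.6% for MT-CO3, 17.9% for MT-ND6, 4.76% for MT-ND5 and 0% for MT-ND3. Nuclear-encoded oxidative phosphorylation genes had 15 of 34 lower and 2 higher, a count that did not change adjusted over the list alone, with ATP5MC1 (-1.33) and ATP5F1B (-0.73) among those that fell (adjusted p = 0.0277 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.477 with an estimated correlation). Without DMSO replicate 2 the oxidative phosphorylation list had an adjusted p = 0.0557 by camera with Benjamini-Hochberg adjustment.

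With SB505124, 21 of 22 p53 target genes rose and 1 fell, PMAIP1 (-0.80, chosen after its values were seen), with the same counts adjusted over the list alone. TP53INP1 (2.61), BBC3 (2.43), the growth arrest gene GADD45A (1.69) and ZMAT3 (1.87) had the smallest p-values, and the median change was 1.19 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.17e-20; adjusted p = 0.109 with an estimated correlation). In the unfolded protein and integrated stress response, 18 of 26 genes rose and 5 fell, as they did adjusted over the list alone. The endoplasmic reticulum chaperone HSPA5 rose from 664 ± 38.4 to 2366 ± 128 CPM (1.83), with DNAJB9 (2.42), PPP1R15A (2.39) and TRIB3 (1.91) also higher (adjusted p = 2.57e-07 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.477 with an estimated correlation). The mitochondrially encoded genes, listed as a possible sign of RNA quality, had a median of -1.27 in these libraries. Their direction was opposite to that with ITD1, while the p53 and stress response lists rose with each compound. Ribosomal protein genes rose, 29 of 40 and 30 adjusted over the list alone, led by RPS27 (1.03) and RPL15 (0.92), with an adjusted p = 5.04e-06 by camera with Benjamini-Hochberg adjustment, or an adjusted p = 0.559 with an estimated correlation.

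Ribosome biogenesis and MYC target genes fell with SB505124, 22 of 28 lower and 2 higher (23 and 2 adjusted over the list alone). The box C/D proteins NOP56 (-1.26) and NOP58 (-1.46) and the pseudouridine synthase DKC1 (-1.26) were among them (camera with Benjamini-Hochberg adjustment, adjusted p = 2.34e-09; adjusted p = 0.109 with an estimated correlation). Of the 32 cell cycle genes 24 fell and 1 rose, also adjusted over the list alone, with CCND1 (-1.70), BUB1B (-1.15) and RRM2 (-1.07) lower (adjusted p = 1.97e-07 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.109 with an estimated correlation). BMP targets and components had 13 of 22 lower and 1 higher (14 and 1 adjusted over the list alone): ID2 fell from 210.2 ± 7.23 to 42.6 ± 3.81 CPM (-2.30), and DLX2 (-2.18), HEY1 (-1.33) and HES1 (-1.10) fell (adjusted p = 2.42e-05 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.109 with an estimated correlation).

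Groups of DNA repair and purine genes had more lower than higher members with SB505124. Of 19 deaminase and purine salvage genes 10 fell and 1 rose, also adjusted over the list alone, with the salvage enzymes APRT (-1.43), PNP (-1.10) and HPRT1 (-0.88) lower and ADAR at -0.11, not called (adjusted p = 0.0417 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.324 with an estimated correlation). ADAR was at 0.027 without SB505124 replicate 1, and it was called without SB505124 replicate 2 (-0.26) and after the GC and length correction (-0.22), which put HPRT1 at -0.58. Mismatch repair had 11 of 20 lower and 2 higher (12 and 2 adjusted over the list alone), with POLD3 (-0.88) and POLD2 (-0.84) lower (adjusted p = 0.0351 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.324 with an estimated correlation). Neither call held without DMSO replicate 2 or either ITD1 replicate: by camera with Benjamini-Hochberg adjustment the adjusted p was 0.0595 without DMSO replicate 2, 0.0505 without ITD1 replicate 1 and 0.0504 without ITD1 replicate 2 for purine salvage and 0.0607 without DMSO replicate 2, 0.0505 without ITD1 replicate 1 and 0.0504 without ITD1 replicate 2 for mismatch repair. The count of lower purine genes was 6 without DMSO replicate 1 and 5 without DMSO replicate 2. In base excision repair 3 of 23 rose and 10 fell, as they did adjusted over the list alone: the inosine-specific endonuclease ENDOV rose from 23.6 ± 1.79 to 59.5 ± 4.89 CPM (1.33), the glycosylase NTHL1 fell (-1.04), and MPG was at 0.26, not called. That list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.407), nor did double-strand break repair (adjusted p = 0.0626), in which 20 of 39 genes fell and 3 rose (20 and 4 adjusted over the list alone), with XRCC5 at -0.71. Lower double-strand break repair genes numbered 10 without DMSO replicate 1 and 12 without DMSO replicate 2, with an adjusted p of 0.00047 without SB505124 replicate 1 by camera with Benjamini-Hochberg adjustment. Lower base excision repair genes numbered 6 without DMSO replicate 1.

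TGF-beta targets went both ways with SB505124: 10 of 27 rose and 7 fell, also adjusted over the list alone. SKIL (-1.03), CCN2 (-0.82), COL1A1 (-1.45) and BMF (-1.94) fell. CDKN1A (1.501), HMOX1 (1.32) and PMEPA1 (0.63) rose, and SMAD7 (-0.27, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.134) was not called. CDKN1A is shared with the p53 list and HMOX1 with the NRF2 list. SMAD7 was called without SB505124 replicate 2 (-0.38) and after the GC and length correction (-0.41), and was at -0.14 without DMSO replicate 2 and -0.15 without SB505124 replicate 1. Pathway components had 10 of 29 higher and 11 lower (11 and 11 adjusted over the list alone), with GDF15 (2.47) higher and GDF11 (-1.39) and SMAD6 (-1.75) lower. Neither list passed camera with Benjamini-Hochberg adjustment (adjusted p = 0.649 and 0.868). The receptor TGFBR1 was at 0.28, called in 6 of 14 alternative settings and lost without either DMSO replicate, either ITD1 replicate or SB505124 replicate 1 (from 0.165 to 0.371). The call of CCN2 was lost with DESeq2 (-0.81), without DMSO replicate 1 (-0.50) and without SB505124 replicate 2 (-0.58), and that of ID1 without DMSO replicate 2 (-0.56). ID1 (-0.83) and CYP1A1 (-1.84) fell and ID3 was at -0.26, not called.

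Other lists had called members in both directions or did not pass as a whole. Wnt targets had 8 of 14 lower with SB505124, LGR5 (-1.35) and LEF1 (-0.71) among them, and interferon genes 8 of 22 higher, ISG15 (2.15) first. NRF2 targets had 10 of 18 higher and 4 lower, extracellular matrix genes 9 of 32 higher and 13 lower, with ACTA2 (1.96) higher and FN1 (-1.28) lower, and immediate early genes 7 of 25 higher, FOSL2 (2.76) first, and 9 lower. Markers of fibroblasts had 5 tested members, of which COL1A1 and PDGFRA (-2.17) fell, and those of kidney epithelium, endothelium and immune cells had 3, 3 and 2. In kidney epithelium LRP2 fell (-2.48) while CUBN (1.68) and AQP1 (1.92) rose from under 2 CPM. Lower Wnt targets numbered 4 without DMSO replicate 1, 5 without DMSO replicate 2 and 5 without SB505124 replicate 1. Higher interferon genes numbered 5 without DMSO replicate 2 and 5 without SB505124 replicate 2 and lower matrix genes 7 without DMSO replicate 2. NRF2 targets had an adjusted p of 0.0361 without SB505124 replicate 1 by camera with Benjamini-Hochberg adjustment. The call of PDGFRA was lost without DMSO replicate 1 (-1.72) and without SB505124 replicate 2 (-1.48), and its change was -3.93 without SB505124 replicate 1. That of AQP1 was lost without DMSO replicate 2 (1.37), and its change was 2.93 without DMSO replicate 1.

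**Figure D1:**
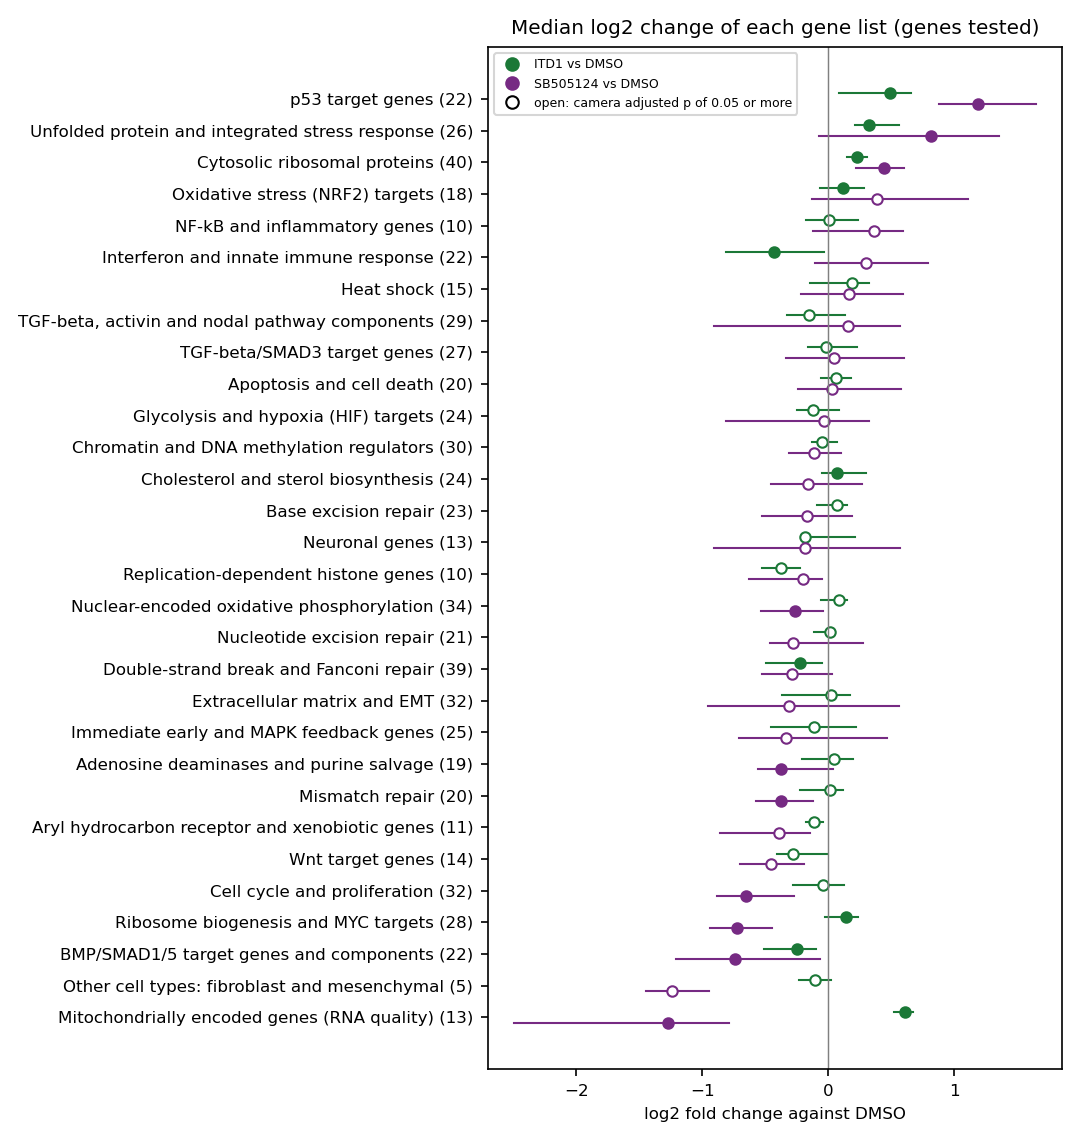
Median log2 fold change against DMSO (horizontal axis) of each gene list with at least 5 tested members (vertical axis, number tested in parentheses), for ITD1 (green) and SB505124 (purple), with bars from the lower to the upper quartile of members. Filled points passed camera with its preset correlation, and the p53 targets lie at 0.49 and 1.19, the mitochondrially encoded genes at 0.61 and -1.27.

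Over the 14000 tested genes 7400 were called with SB505124, 3689 higher and 3711 lower, of which 2023 changed by at least 2-fold. Of 30 lists tested, 10 passed camera with its preset correlation for each compound and 0 with an estimated correlation, where 3 with ITD1 and 5 with SB505124 had an unadjusted p under 0.05; fry, a test of each list against no change, passed 5 and 16. The SB505124 replicates differed more than the others, by a median of 0.22 on the log2 scale per gene against 0.098 in DMSO and 0.11 in ITD1.

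The third comparison set the compounds side by side. ANKRD1 was higher in SB505124 than in ITD1 by 6.88 on the log2 scale (SE 0.18), followed by DNAH17 (3.57), NECTIN4 (3.30), FLNC (3.06) and INPP5D (2.72). MT-ND6 (-3.86), MT-CO3 (-3.48), ZNF503 (-3.16), MT-ND5 (-3.07) and MT-CO1 (-2.94) were lower in SB505124. The mitochondrially encoded genes differed in 12 of 13 members downward and 1 upward, also adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 4.8e-36; adjusted p = 0.132 with an estimated correlation). Ribosome biogenesis genes were lower in 24 of 28, p53 targets higher in 19 of 22 and lower in 1, and cell cycle genes lower in 19 of 32 and higher in 1, each with the same counts adjusted over the list alone (adjusted p = 6.12e-13, 3.62e-10 and 1.5e-05 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.132, 0.132 and 0.162 with an estimated correlation). Interferon genes were higher in 10 of 22, and nuclear-encoded oxidative phosphorylation genes lower in 21 of 34 and higher in 2 (3 higher adjusted over the list alone, the other counts unchanged), with an adjusted p = 0.00552 and 0.00357 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.31 for both with an estimated correlation). Purine salvage genes were lower in 8 and higher in 2 of 19, BMP genes lower in 8 and higher in 2 of 22, and stress response genes higher in 15 and lower in 7 of 26 (16 higher adjusted over the list alone). Their adjusted p was 0.0191, 0.0254 and 0.0196 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.304, 0.304 and 0.74 with an estimated correlation). By camera with Benjamini-Hochberg adjustment the adjusted p was 0.106 without SB505124 replicate 2 for interferon genes, 0.0771 without SB505124 replicate 2 for BMP genes, and 0.0614 without ITD1 replicate 1 and 0.0552 without SB505124 replicate 2 for stress response genes, and lower oxidative phosphorylation genes numbered 13 without ITD1 replicate 2. In all 7457 genes were called, 3893 higher and 3564 lower in SB505124.

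Of the genes called with ITD1, 48.3% were called in the same direction with SB505124: 257 higher and 356 lower with both, where independent lists would share 139 and 196. A further 173 genes were called in opposite directions, against 335 for independent lists. With unchanged groups simulated against the same DMSO libraries, the mean number shared in one direction was 0.02 higher and 0.04 lower. Unchanged groups give few calls to share, so these values are no reference for lists of this size. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.274 and a Spearman correlation of 0.281. The simulated unchanged groups gave 0.507 and 0.466 from the shared controls alone. Real changes widen the spread of the log2 values and were absent there, so the observed correlations cannot be ranked against the simulated ones. The covariance was 0.0874 against a simulated 0.0298, a difference of 0.0576. The simulated libraries had 1 spread per gene in all groups, while chi-square per degree of freedom was 2.66 in DMSO and 18.9 in SB505124. The simulated correlations and covariance are therefore not a measure of what these DMSO libraries contribute. With 2 DMSO libraries the controls were not split, so part of the excess over independent lists may come from the shared controls. Part may also come from GC content, since the GC trend against DMSO had the same sign for ITD1 (-0.47) and SB505124 (-0.35). That of SB505124 came mostly from replicate 2. After the GC and length correction 999 genes were called in the same direction and 342 in opposite directions. Each comparison then had more calls (1882 and 8459), so these counts do not decide it. The same-direction count was 1 without DMSO replicate 1, 11 without DMSO replicate 2, 105 without ITD1 replicate 1, 10 without ITD1 replicate 2, 2794 without SB505124 replicate 1 and 1840 without SB505124 replicate 2.

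**Figure D2:**
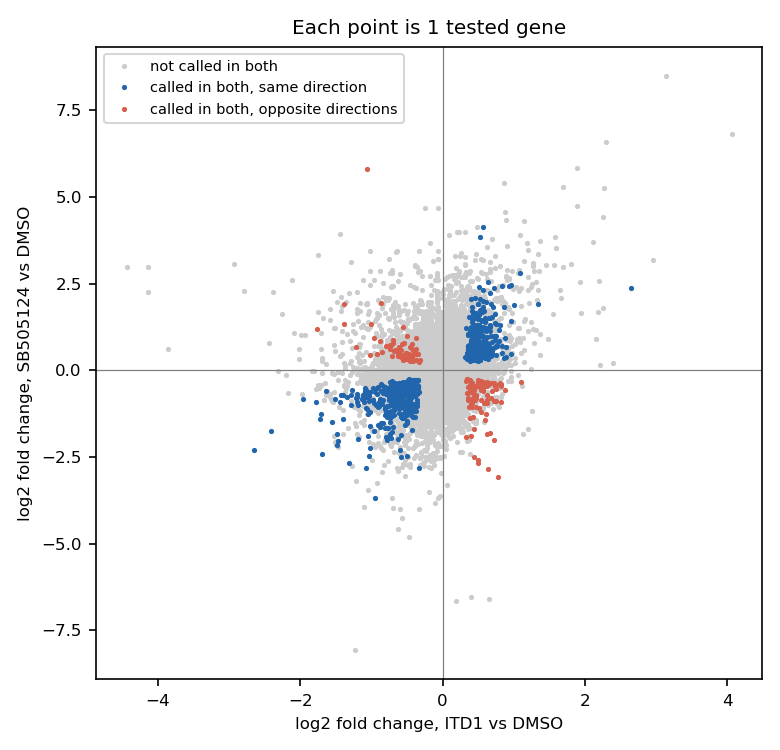
Log2 fold change against DMSO of each of 14000 tested genes with SB505124 (vertical axis) against ITD1 (horizontal axis). Blue points are the 613 genes called in the same direction with both compounds, red points the 173 called in opposite directions, and grey points all others.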

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

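The tests of mitochondrial genes with few annotated copies and of the most abundant genes, and the comparison of GC trends between replicates were chosen only after the results were seen, as was every GC and length correction.

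In 173 genes the calls went in opposite directions with ITD1 and SB505124, and each of the 173 was also called in the direct contrast of the compounds, which follows from how they were chosen and adds no support; 104 were higher with ITD1 and lower with SB505124, and 69 the other way. The number was 1 without DMSO replicate 1, 6 without DMSO replicate 2, 23 without ITD1 replicate 1, 7 without ITD1 replicate 2, 749 without SB505124 replicate 1 and 1190 without SB505124 replicate 2. It was 342 after the GC and length correction, 608 with the 4 libraries of each comparison and 5 with a 2-fold minimum. The transferrin receptor TFRC (-1.39 with ITD1 and 1.33 with SB505124) is 1 of them and was chosen after its values were seen.

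In the sheet of SB505124, 7 genes outside the joint fit had 0 counts in both DMSO libraries and over 3 counts in both SB505124 libraries, among them ORM2 (17 and 10), ACTL7A (11 and 11), KRT19 (7 and 11), IHO1 (9 and 5), OVCH1 (5 and 7) and UCP1 (6 and 4). The ITD1 sheet had 0 such genes. Groups of 2 libraries are too small for a test of outlying samples.

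The genes called lower with ITD1 were AT-rich and long. A correction of each library's GC and length trend reduced their median log2 change from -0.61 to -0.38 (95% bootstrap interval -0.40 to -0.36). The interval resampled genes, not libraries. These genes were chosen for being lower in the same libraries, so a negative median was likely to remain whatever the cause. The trend may account for part of the change, and whether it accounts for all of it cannot be decided here. Of 739 genes, 488 were still called lower, a number helped by a smaller median SE (0.14 before and 0.096 after). After a length correction alone 549 were still called. Both counts are of genes chosen in the same libraries and have no reference, so neither excludes GC or length as the only cause. GC trends also varied within a treatment: the SB505124 replicates differed by 0.54 between the lowest and highest decile, more than the 0.47 by which ITD1 lay below DMSO, while the DMSO and ITD1 pairs differed by 0.053 and 0.023. A library effect on AT-rich genes and an effect of ITD1 on them both remain open.

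Of the 13 mitochondrially encoded genes 10 were lower with SB505124 and 1, MT-ND2, was higher. The 10 most abundant genes took at most 5.37% of the counts in an SB505124 library, so a few genes did not take most of the counts. This share was known when the test was chosen. The test replaced scaling without the mitochondrially encoded genes, which moved the values too little to decide the question. The correction for GC and length left the median at -0.94 (from -1.27). The 5 genes with under 5% of 50-base windows in other annotated transcripts had a median of -1.19, which argues against reads shared with annotated copies as the whole cause. Among those with 0% of windows shared, MT-ND4L was at -0.94 and MT-ND3 at 0.064. Nuclear copies outside annotated transcripts were not searched, so reads shared with them cannot be excluded. A lower amount of mitochondrial RNA with SB505124 is a hypothesis that may explain part of the pattern and was found and tested on the same libraries. An equal fall of all 13 genes would not give their spread, with quartiles of -2.50 and -0.79, MT-ND3 near no change and MT-ND2 higher. The source of that spread was not tested. RNA quality and the share of mitochondrial reads captured were not measured.

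The p53 target genes were higher with ITD1. The correction for GC and length left the median of all 22 tested members at 0.43 (from 0.49), which argues against a GC or length trend as the whole cause. Of 12 called members 11 were still called, but these were chosen in the same libraries, so that count has no reference. Leaving out DMSO replicate 1 or 2 left the median at 0.49 and 0.55, which argues against 1 deviating DMSO library as the source of its size, but the number of called members fell to 0 and 1, so the calls of single genes do rest on both. Without SESN2, the 1 member also in the stress response list, the median was 0.43 with 11 of 21 genes higher. Taking out 1 gene of 22 could move the median little whatever the cause. It therefore does not separate a response of p53 targets from a stress response. An effect of ITD1 on p53 target genes stays open as a hypothesis found and tested on the same libraries, as does a stress of the cells that acts on these genes in other ways; neither p53 activity nor cell stress was measured, and HEK293T cells carry the large T antigen, which binds p53.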

How the results depend on the processing

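The corrections for GC and length, the length correction alone and the scaling without mitochondrial genes were chosen after the data were seen, as were all alternatives for the overlap of calls other than DESeq2, the 2-fold minimum and leaving out libraries. With 2 libraries per group, and a lone library assumed to vary like the others when 1 was left out, the ITD1 comparison was the least stable. Its 1268 calls became 97 with a 2-fold minimum, from 3 to 4837 without 1 library and 4534 with the 4 libraries of the comparison. Leaving out a DMSO or ITD1 library leaves fewer samples, and leaving out an SB505124 library removes the pair that spreads most, so the shared spread falls. The SB505124 count of 7400 became 2023, and that of the direct contrast 7457 became 1883, with a 2-fold minimum; without 1 library they ran from 5175 to 8649 and from 5184 to 8355. The 613 genes shared in direction became 25 with a 2-fold minimum, from 1 to 2794 without 1 library, 1807 with 4 libraries and 999 after the GC and length correction; the cause of the last was not tested. With an estimated correlation 0 lists passed in each comparison, against 10, 10 and 9. The 3 residual degrees of freedom that camera then uses made passing unlikely beforehand. For BMP genes with ITD1 the estimated correlation was -0.0125, below the preset 0.01, yet the unadjusted p by camera went from 1.02e-05 to 0.0167. The loss therefore does not show that correlation between genes undid these results.

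RLE scaling, either other filter and DESeq2 kept the 3 counts within 1.5 times. DESeq2 called 695 higher and 632 lower with ITD1 and the GC and length correction 1069 and 813, so the share of higher calls moved from 41.7% to 52.4% and 56.8%. No scaling moved the median of all genes by over 0.1. A replicate block, for numbers whose deviations correlated by 0.031, 0.042 and 0.053 between groups and which therefore do not pair the libraries, gave 1680, 7512 and 7542 calls.

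Among named genes, the change of TGFBR1 with ITD1 turned to 0.048 after the GC and length correction, CCN2 with ITD1 to 0.034 without DMSO replicate 1 (lowest without 1 library -0.49), and ADAR with SB505124 to 0.027 without SB505124 replicate 1. None of the turned values was called, and the cause was not tested. ADAR was called without SB505124 replicate 2 (-0.26) and after the GC and length correction (-0.22). A call was lost in 240 gene and setting pairs with ITD1, 27 with SB505124 and 0 in the direct contrast. In the self-test, run at the observed depth with 2 libraries per group, 66.1% of 1.5-fold changes were recovered with ITD1 and 54.1% with SB505124. Depth was not varied, so this sets no limit of depth. The simulated groups shared 1 spread per gene, unlike the observed ones, so these shares may not hold for the observed comparisons. The planned change of pseudocount was not run, since the sheets hold counts.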

Other observations

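The gene families and genes here were chosen after the values of the named genes were seen, and so were the GC and length corrections applied to them. Of 12 families tested, 6 passed camera with ITD1 and 6 with SB505124, and 1 and 0 with an estimated correlation. N-glycan assembly, the building of the sugar chain that is put on proteins in the endoplasmic reticulum, was higher with ITD1: 12 of 28 genes rose and none fell, among them ALG3 (0.96), ALG1 (0.88), RPN1 (0.84), ALG8 (0.73) and STT3A (0.65). Camera with Benjamini-Hochberg adjustment over 12 families gave an adjusted p = 8.94e-12, or an adjusted p = 0.0474 with an estimated correlation. ALG3 and ALG1 are named genes whose values were seen before the family was chosen. Without them 10 of 26 genes were higher, with an adjusted p = 5.45e-09 by camera with Benjamini-Hochberg adjustment, or an adjusted p = 0.0764 with an estimated correlation. The median of these 26 was 0.26. The median of all 28 genes, 0.31, was 0.43 after the correction. The count of higher genes was 0 without DMSO replicate 1, 2 without DMSO replicate 2, 5 without ITD1 replicate 1, 2 without ITD1 replicate 2, 18 without SB505124 replicate 1 and 18 without SB505124 replicate 2. With SB505124, 9 of these genes rose and 5 fell. Lysosomal genes rose in 12 of 27 with ITD1, such as CTSA (0.64) and GAA (0.51), with an adjusted p = 3.51e-11 by camera with Benjamini-Hochberg adjustment and an adjusted p = 0.123 with an estimated correlation. Their count was 0 without DMSO replicate 1, 0 without DMSO replicate 2, 2 without ITD1 replicate 1, 0 without ITD1 replicate 2 and 20 without SB505124 replicate 1.

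HOX genes, the positional transcription factors, fell with SB505124 in 25 of 36 and rose in 1, with HOXC4 (-2.01), HOXA5 (-1.72) and HOXB3 (-1.83) lower and a median of -0.89, which was -0.89 after the correction. Camera with Benjamini-Hochberg adjustment gave an adjusted p = 7.34e-12 (adjusted p = 0.093 with an estimated correlation), and with ITD1 edgeR called 0 of the 36 genes, 6 had an unadjusted p under 0.05 and DESeq2 called 0. Mitochondrial ribosomal protein genes fell in 37 of 74 and rose in 6, MRPL28 (-1.11) and MRPL1 (-1.14) among the lower, and 26 without DMSO replicate 1 and 23 without DMSO replicate 2 fell. The CCT chaperonin subunits fell in 7 of 9, CCT5 (-0.81) first. These lists passed camera with Benjamini-Hochberg adjustment at an adjusted p = 0.0029 and 0.0139, and had an adjusted p = 0.449 and 0.449 with an estimated correlation. The other families that passed camera were, with ITD1, proteasome (1 of 35 higher), vacuolar ATPase (3 of 20 higher, 1 lower), mitochondrial ribosomal (1 of 74 higher) and kinesin and centromere genes (14 of 55 lower, 1 higher). With an estimated correlation camera with Benjamini-Hochberg adjustment gave these an adjusted p = 0.391, 0.221, 0.391 and 0.123. At the preset correlation the adjusted p by camera with Benjamini-Hochberg adjustment was 0.0974 without ITD1 replicate 2 for the proteasome, 0.0934 without DMSO replicate 1 and 0.0506 without ITD1 replicate 2 for the vacuolar ATPase and 0.0506 without ITD1 replicate 2 for mitochondrial ribosomal proteins. The count of higher genes was 0 without DMSO replicate 1, 0 without DMSO replicate 2, 0 without ITD1 replicate 1, 0 without ITD1 replicate 2, 18 without SB505124 replicate 1 and 15 without SB505124 replicate 2 for the proteasome, 0 without DMSO replicate 1, 1 without DMSO replicate 2, 1 without ITD1 replicate 1, 1 without ITD1 replicate 2, 9 without SB505124 replicate 1 and 9 without SB505124 replicate 2 for the vacuolar ATPase, and 0 without DMSO replicate 1, 0 without DMSO replicate 2, 0 without ITD1 replicate 1, 0 without ITD1 replicate 2, 30 without SB505124 replicate 1 and 21 without SB505124 replicate 2 for mitochondrial ribosomal proteins. Lower kinesin and centromere genes numbered 0 without DMSO replicate 1, 0 without DMSO replicate 2, 7 without ITD1 replicate 1, 0 without ITD1 replicate 2, 20 without SB505124 replicate 1 and 22 without SB505124 replicate 2. Higher ones numbered 0 without DMSO replicate 1, 0 without DMSO replicate 2, 0 without ITD1 replicate 1, 0 without ITD1 replicate 2, 10 without SB505124 replicate 1 and 7 without SB505124 replicate 2. Without CENPE, CENPF and KIF20B, named genes also seen beforehand, 11 of 52 were lower, with an adjusted p = 0.0253 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.207 with an estimated correlation). The genes called lower with ITD1 had a median GC content of 39.4% against 48.7% for tested genes. Values of the kinesin and centromere family after the GC and length correction are not given here, so a GC or length trend remains open for it.

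With SB505124 the others were kinesin and centromere genes (26 lower, 7 higher; 17 without DMSO replicate 1 were lower, and 4 without DMSO replicate 2 and 11 without SB505124 replicate 1 higher), tRNA synthetases (19 of 37 lower, 2 higher) and iron genes (7 of 12 higher, 2 lower). With an estimated correlation camera with Benjamini-Hochberg adjustment gave these an adjusted p = 0.288, 0.449 and 0.449. Without the genes named in the comparisons, camera with Benjamini-Hochberg adjustment gave kinesin and centromere genes an adjusted p = 0.0497 and iron genes an adjusted p = 0.202.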
